A study of Mus musculus with 40 samples.

How the data were processed

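RNA was sequenced from 40 EMT-6 tumors, 1 library per mouse, in 4 treatment groups of 10. Per the labels, tumors were snap-frozen, total RNA was extracted, and libraries were made after ribosomal depletion with random priming. The submitters' processing notes name RSEM 1.2.31, Bowtie2 2.3.1 and the mm10 genome, without saying which tool did what or in which order. The annotation release, trimming and any filter were not stated.

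The authors deposited a table of RSEM expected counts and a table of TPM, each for 39012 Ensembl genes and all 40 libraries. Expected counts share reads that map to several genes between them, and 14.0% of the values were not whole, so they were rounded for the fits. TPM values divide by transcript length and sum to the same total in every library. Gene IDs were matched to GENCODE M21 symbols, which covered 37607 IDs or 96.4%. The strand used in counting was not stated.

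Total expected counts ran from 13495835 to 27658263 per library with a median of 24018639, and each value's precision follows from the library it came from. No 2 libraries of a group were duplicates, since the smallest chi-square per degree of freedom between any pair was 9.60.

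Genes were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood F test, two-sided, after TMM scaling and the default filter on low counts by group. All 40 libraries entered 1 fit with a mean per group, which kept 15183 genes. The 5 pairwise comparisons and the interaction of the 2 arms (the difference bifunctional minus anti-PD-L1, less the difference trap control minus isotype control) were contrasts of this fit. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are on the log2 scale with their SE, and CPM values are TMM-scaled means with SD over 10 libraries unless another number is given.

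Gene lists for 37 cell types, pathways and host tissues (507 entries, some genes in more than 1 list) were written before the data were examined, as were the comparisons, the tests and the alternative settings listed last. Each list was tested against all other genes with camera in limma 3.58.1, with a preset correlation between genes of 0.01, two-sided, and Benjamini-Hochberg adjustment over the lists of a comparison. camera was also run with the correlation estimated from the data, and fry tested each list by itself. In the fit of all libraries 36 lists had enough measured members. Members that rose or fell were counted from the edgeR test, adjusted over all genes and adjusted over the list alone. A list score is the mean over its members of log2(CPM + 1) in 1 library. To compare the folds of lists with different levels, each gene was also divided by its mean over the 20 libraries compared, averaged over the list and put on the log2 scale, a measure chosen after the results were seen. Scores were compared by two-sided permutation tests with 100000 resamples where both groups held 10 libraries, and by exact permutation tests otherwise. These used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3; plots were drawn with matplotlib 3.10.9.

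The genes named in the text come from a rule written before the data were examined. In each comparison it took, among genes with adjusted p under 0.05 and a mean of at least 1 CPM in a group compared, the 8 largest rises and the 8 largest falls, leaving out predicted genes, small RNAs and pseudogenes. It added up to 4 members of each list that was called or held a called member, by smallest adjusted p, together with Cd274, Pdcd1, Tgfb1, Tgfb2, Tgfb3, Tgfbr1 and Tgfbr2. The text names part of these, and some genes whose change rested on 1 library were left out.

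The libraries turned out to fall into sets by their share of 7SL and mitochondrial ribosomal RNA, with a threshold of 25% of counts. The labels name no batch. After this was seen, each comparison was repeated within a set where both groups had libraries there, or with the set as a term in the fit of all libraries. Other alternatives added after seeing the data were the structural RNA share as a covariate, leaving those RNAs out, leaving out libraries that stood apart, the groups compared together with host tissue covariates, a fit of the 3 groups of set 2, and removal of a trend with GC content. That trend was removed by shifting each gene in each library by a smooth curve over the GC content of its transcripts.

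The alternative settings chosen beforehand were DESeq2 size factors in place of TMM, no filter, a mean of at least 1 CPM as filter, the DESeq2 1.42.0 Wald test, a fit of only the groups compared, scores of skeletal muscle, skin and adipocyte lists as covariates, log2(TPM + 1) and log2(TPM + 0.1) in limma, the estimated correlation, fry, and the median over members in place of the mean. Each count of genes was also set against 40 splits of the same libraries into groups of the same sizes, the real split included. The procedures were tested on simulated data with known changes. Correlations of list scores were computed within a group and library set, and no library was left out of the values given first.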

Results

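Gene expression was measured by bulk RNA sequencing in 40 EMT-6 tumors, 1 library per mouse. EMT-6 is a mouse mammary carcinoma cell line that grows in Balb/C mice. Cells were placed in the mammary pad, and dosing began 20 days later at a mean tumor volume of about 400 mm3. Mice were dosed intravenously on days 0, 1 and 2, and tumors were taken on day 6. The groups of 10 received an inactive anti-PD-L1 isotype control (400 µg), a trap control in which a PD-L1 antibody mutated to lose binding carries the TGF-β trap (492 µg), anti-PD-L1 (400 µg), or a bifunctional protein that joins anti-PD-L1 to the TGF-β trap (492 µg). PD-L1 is a ligand that restrains T cells through the receptor PD-1, and TGF-β is a cytokine that restrains immune cells and stimulates matrix production. Total expected counts per library ran from 19341474 to 24040660 in the isotype control group, 13495835 to 26389345 with the trap control, 23645117 to 27191617 with anti-PD-L1 and 22793662 to 27658263 with the bifunctional protein. Between 18197 and 21526 genes were detected per library.

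The libraries formed separate sets by the RNA they contained, and the sets followed the sample numbers. The RNAs Rn7s1 and Rn7s2 (7SL RNA of the signal recognition particle) and mt-Rnr1 and mt-Rnr2 (mitochondrial ribosomal RNA) together took 29.7% to 62.3% of counts, median 43.3%, in the 16 libraries C0449 to C0464. The same RNAs took 11.7% to 18.0%, median 14.4%, in the 24 libraries C0465 to C0488. Rn7s1 and Rn7s2 had identical counts in all 40 libraries. The share of protein-coding genes ran from 24.5% to 59.0% in the 16 libraries, called set 1 from here on, and from 71.2% to 79.6% in the 24 libraries of set 2. Set 1 held all 10 isotype control libraries and 6 trap control libraries. Set 2 held the other 4 trap control libraries and all 20 libraries of the anti-PD-L1 and bifunctional groups. The first principal component carried 73.1% of the variance over 11258 genes. It was computed on log2(CPM + 1) without TMM scaling, so the share of structural RNA itself shifts the values of all other genes in it. Within the trap control group alone, edgeR called 6997 of 14456 genes between the 6 and the 4 libraries, 3627 of them higher in set 1. Comparisons across sets therefore carry this difference, and values within a set or with the set as a term stand beside the pooled ones.

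**Figure D1:**
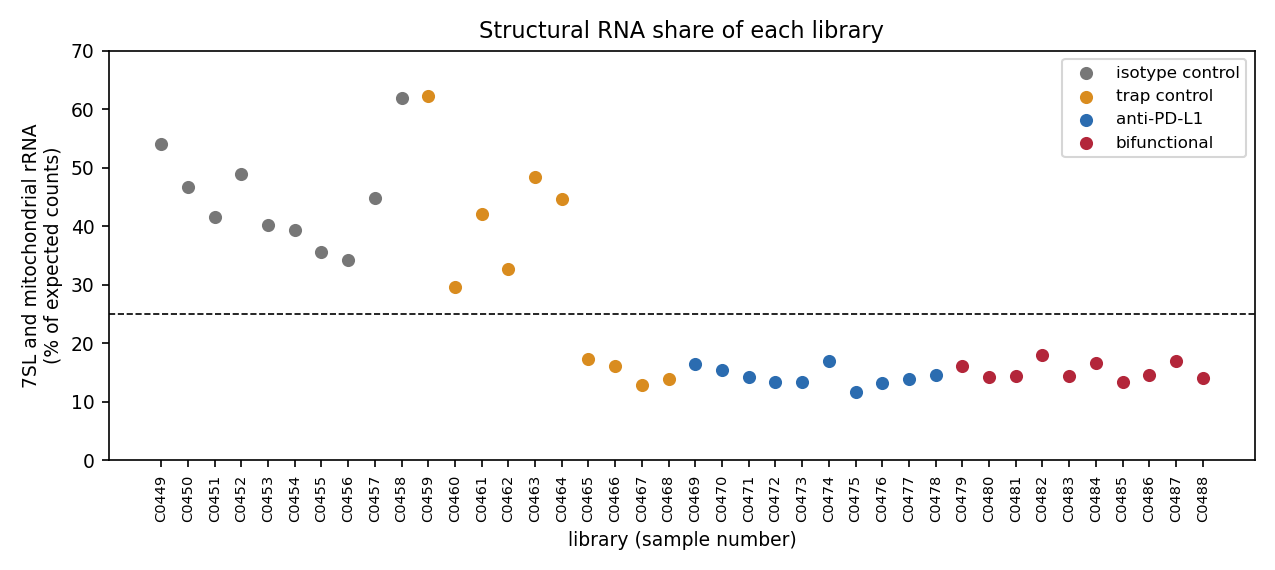
Share of expected counts in 7SL and mitochondrial ribosomal RNA (vertical axis, %) for each of the 40 libraries in order of sample number, 1 point per library, coloured by treatment group; the dashed line marks 25%. Libraries C0449 to C0464 lie between 29.7% and 62.3%, and libraries C0465 to C0488 between 11.7% and 18.0%.

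The comparison of the bifunctional protein with anti-PD-L1 asks what the TGF-β trap adds to PD-L1 blockade, and both groups lie in set 2. Sample numbers follow treatment there too, with anti-PD-L1 at C0469 to C0478 and the bifunctional protein at C0479 to C0488. A processing difference between these runs of numbers cannot be told apart from treatment. Genes of cytotoxic lymphocytes were higher in bifunctional tumors. Gzmb (ENSMUSG00000015437, mm10 chromosome 14, 56258838 to 56262260), which encodes the granule protease granzyme B, rose by 2.03 on the log2 scale (SE 0.299, edgeR adjusted p = 0.000601). It reached 4.31 ± 1.49 CPM (SD, n = 10) against 1.05 ± 0.492 CPM with anti-PD-L1, and all 10 bifunctional libraries lay above the anti-PD-L1 median. Prf1, the pore-forming protein perforin, rose by 2.05 (SE 0.373, adjusted p = 0.00423), from 1.19 ± 0.762 to 4.93 ± 2.49 CPM, in 10 of 10 libraries. Nkg7, a protein of cytotoxic granules, rose by 1.86 (adjusted p = 0.0031), and Gzme, a granzyme with near-identical paralogs, by 2.03 (adjusted p = 0.0072). Of the 13 measured cytotoxic effectors 9 rose, 11 when adjusted over the list alone, with a median log2 fold change of 1.86. camera called the list (bifunctional vs anti-PD-L1, adjusted p = 8.01e-10), a call lost with an estimated correlation (adjusted p = 0.0803). The cytotoxic score was 1.920 ± 0.297 in bifunctional tumors and 1.066 ± 0.261 in anti-PD-L1 tumors (n = 10 each, permutation adjusted p = 0.00048, 10 of 10 libraries above the anti-PD-L1 median). The same score was 0.918 ± 0.256 in the isotype control tumors, whose libraries are of set 1.

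T cell genes moved the same way. Of 15 measured T cell genes 9 rose (12 adjusted over the list alone), with a median of 1.15. Zap70, the kinase of the T cell receptor, rose by 1.27 (SE 0.22, adjusted p = 0.00292). The surface receptors Cd6 and Cd28 rose by 1.76 (adjusted p = 0.00573) and 1.53 (adjusted p = 0.00741). Cd6 was low, with a median log2(CPM + 1) of 0.217 in the anti-PD-L1 libraries other than C0473, so its fold rests on few reads. Of the 7 regulatory T cell genes 5 rose, and 5 adjusted over the list alone, with a median of 1.11; they include Ctla4, an inhibitory receptor, at 1.83 (SE 0.419, adjusted p = 0.00959). Of 6 NK cell genes 3 rose (6 adjusted over the list alone, median 1.07), among them the activating receptor Ncr1 at 1.29 (SE 0.384, adjusted p = 0.0274). Of 8 inhibitory receptors 1 rose (3 adjusted over the list alone, median 0.68). For bifunctional vs anti-PD-L1 camera called these 4 lists, with adjusted p = 3.44e-07 for T cells, 0.00142 for regulatory T cells, 0.000436 for NK cells and 0.0238 for inhibitory receptors. None of these calls held with an estimated correlation (adjusted p = 0.169 for T cells and regulatory T cells, 0.204 for NK cells, 0.34 for inhibitory receptors). In the 20 libraries compared, with a GC trend removed, inhibitory receptors were no longer called (camera adjusted p = 0.0784). The T cell score was 1.132 ± 0.225 against 0.763 ± 0.090 (n = 10 each, permutation adjusted p = 0.00054, 10 of 10 libraries above).

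**Figure D2:**
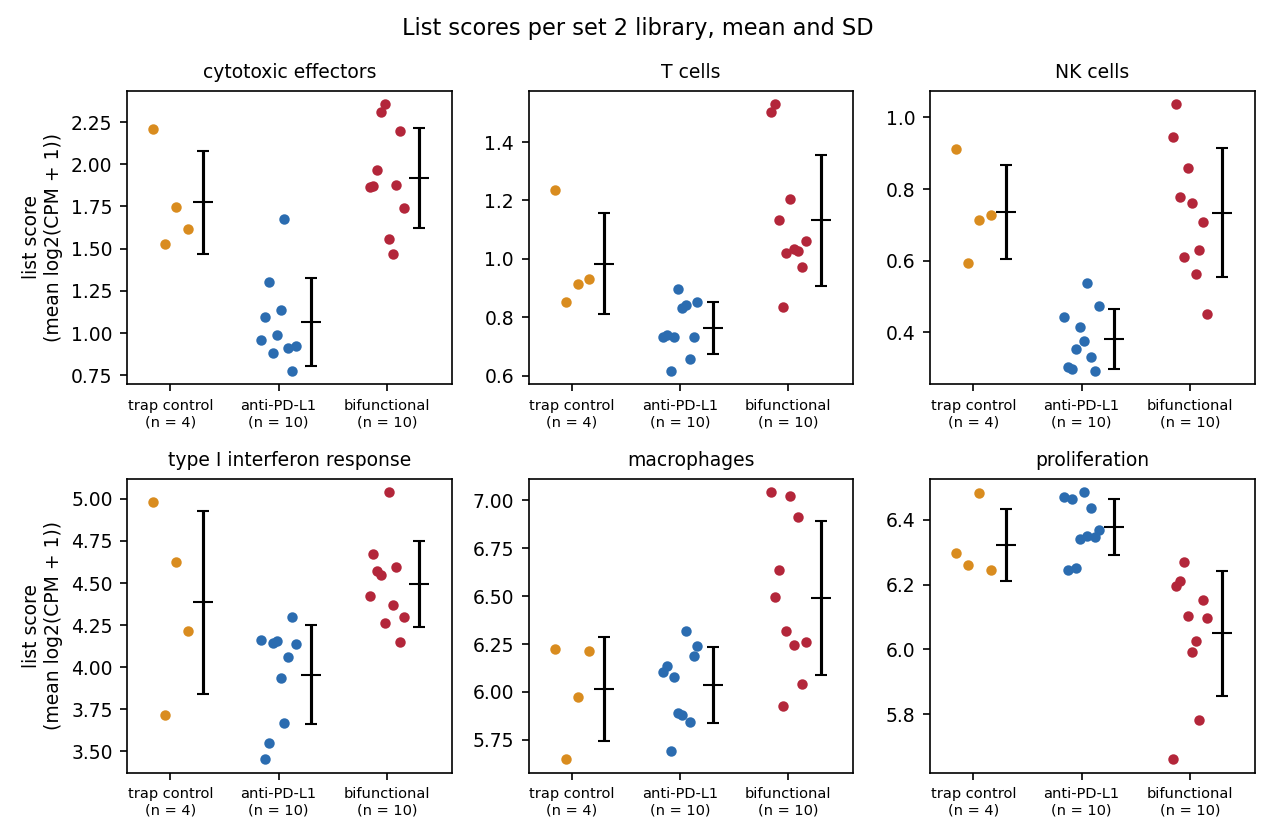
List scores (vertical axis, mean log2(CPM + 1) over the members of a list) of the set 2 libraries: 4 trap control, 10 anti-PD-L1 and 10 bifunctional, 1 point per library, with mean and SD as bars and each panel on its own scale. The cytotoxic score averages 1.920 with the bifunctional protein, 1.066 with anti-PD-L1 and 1.775 in the 4 trap control libraries; the proliferation score averages 6.049 with the bifunctional protein and 6.376 with anti-PD-L1.

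Interferon-induced genes were higher as well. Of 21 type I interferon genes 11 rose (18 adjusted over the list alone), with a median of 0.63. Irf7, a transcription factor of the interferon response, rose by 0.81 (SE 0.169, adjusted p = 0.007), from 29.9 ± 7.86 to 52.3 ± 10.1 CPM (n = 10 each), in 10 of 10 libraries. The antiviral enzyme Oas3 rose by 0.74 (adjusted p = 0.014) and the nucleic acid sensor Zbp1 by 0.71 (adjusted p = 0.0172). Of 20 interferon-γ genes 8 rose (9 adjusted over the list alone), with a median of 0.47. Of 9 chemokines that attract T cells 4 rose (6 adjusted over the list alone, median 0.87); Cxcl9 rose by 1.28 (adjusted p = 0.0472) and Cxcl10 by 0.74 (adjusted p = 0.0449). For bifunctional vs anti-PD-L1 camera called these 3 lists (adjusted p = 8.01e-10 for type I interferon, 0.000176 for interferon-γ and 0.00068 for chemokines), without a call at an estimated correlation (adjusted p = 0.297, 0.421 and 0.187). Cxcl9 and Cxcl10 lie near the threshold: with no filter their adjusted p was 0.066 and 0.0665. None of the 13 MHC class I presentation genes rose at adjusted p under 0.05 over all genes (median 0.10, camera adjusted p = 0.796).

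Among myeloid genes, 9 of 15 macrophage genes rose (11 adjusted over the list alone), with a median of 0.50. C1qb, a subunit of complement C1q made by macrophages, rose by 0.75 (SE 0.174, adjusted p = 0.0104), from 61.4 ± 12.3 to 103 ± 34.8 CPM (n = 10 each). Itgam, the integrin CD11b of myeloid cells, rose by 0.58 (SE 0.141, adjusted p = 0.012), and its adjusted p was 0.061 without libraries C0479 and C0484. Of 11 dendritic cell genes 4 rose (7 adjusted over the list alone, median 0.60) and of 8 MHC class II genes 1 (5 adjusted over the list alone, median 0.77). In bifunctional vs anti-PD-L1 camera called macrophages (adjusted p = 1.27e-05), dendritic cells (0.00537) and MHC class II (0.00298), and none with an estimated correlation (adjusted p = 0.34, 0.297 and 0.421). Without C0479 and C0484, 1 macrophage gene and 0 genes of the other lists passed in edgeR.

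Matrix, stromal and host tissue genes were also higher, and much of this lay in the bifunctional libraries C0479 and C0484. These 2 lay farthest out on the second principal component, at 54.2 and 51.4 with a median of −1.23 for the others. Of 33 collagen and matrix genes 7 rose (8 adjusted over the list alone, median 0.52), and of 14 fibroblast genes 3 (5 adjusted over the list alone, median 0.66). Eln, which encodes elastin, rose by 2.23 (SE 0.478, adjusted p = 0.0072), and the fibroblast receptor Pdgfra by 0.79 (SE 0.185, adjusted p = 0.0104). Col1a1, the main chain of type I collagen, rose by 0.97 (SE 0.264, adjusted p = 0.0195), but among the 20 libraries compared its value was 0.72 (adjusted p = 0.0628) without C0479 and 0.90 (adjusted p = 0.0501) without C0484. Vwf, made by endothelial cells, rose by 1.55 (SE 0.301, adjusted p = 0.00547), and by 0.94 (adjusted p = 0.0323) without both libraries; it is 1 of 12 endothelial genes that rose (3 adjusted over the list alone, median 0.39). Of 6 nerve and Schwann cell genes 1 rose (2 adjusted over the list alone, median 0.78). In bifunctional vs anti-PD-L1 camera called matrix (adjusted p = 0.000215), fibroblasts (0.021), endothelium (0.0273) and nerve (0.0464). With an estimated correlation the adjusted p was 0.421, 0.5, 0.693 and 0.421. In the 20 libraries with a GC trend removed, camera called neither endothelium (adjusted p = 0.0538) nor nerve (adjusted p = 0.0784).

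Keratinocyte and muscle genes gave the highest list medians of the comparison, and some fat genes were higher too. All 4 skin keratinocyte genes rose, 4 adjusted over the list alone, with a median of 4.30, and Krt5, a keratin of basal keratinocytes, rose by 4.87 (SE 1.03, adjusted p = 0.0072). Of 9 skeletal muscle genes 6 rose (9 adjusted over the list alone, median 4.44), including the muscle creatine kinase Ckm at 4.97 (SE 1.65, adjusted p = 0.0416; 0.0554 with no filter). Of 9 adipocyte genes 5 rose (8 adjusted over the list alone, median 1.75). In bifunctional vs anti-PD-L1 camera called none of these 3 lists (adjusted p = 0.487, 0.0504 and 0.118). The scores differed by less than the spread between libraries, with muscle at 2.412 ± 2.979 against 0.645 ± 1.230 (n = 10 each, permutation adjusted p = 0.186). The muscle score was 7.06 in C0479 and 7.99 in C0484, and also 3.31 in C0480 and 3.47 in C0481. Without C0479 and C0484 the keratinocyte median was 0.23 and that of the matrix list 0.23, with 5 of 33 matrix genes higher. Without C0479 alone Krt5 was at 1.46 (adjusted p = 0.163).

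**Figure D3:**
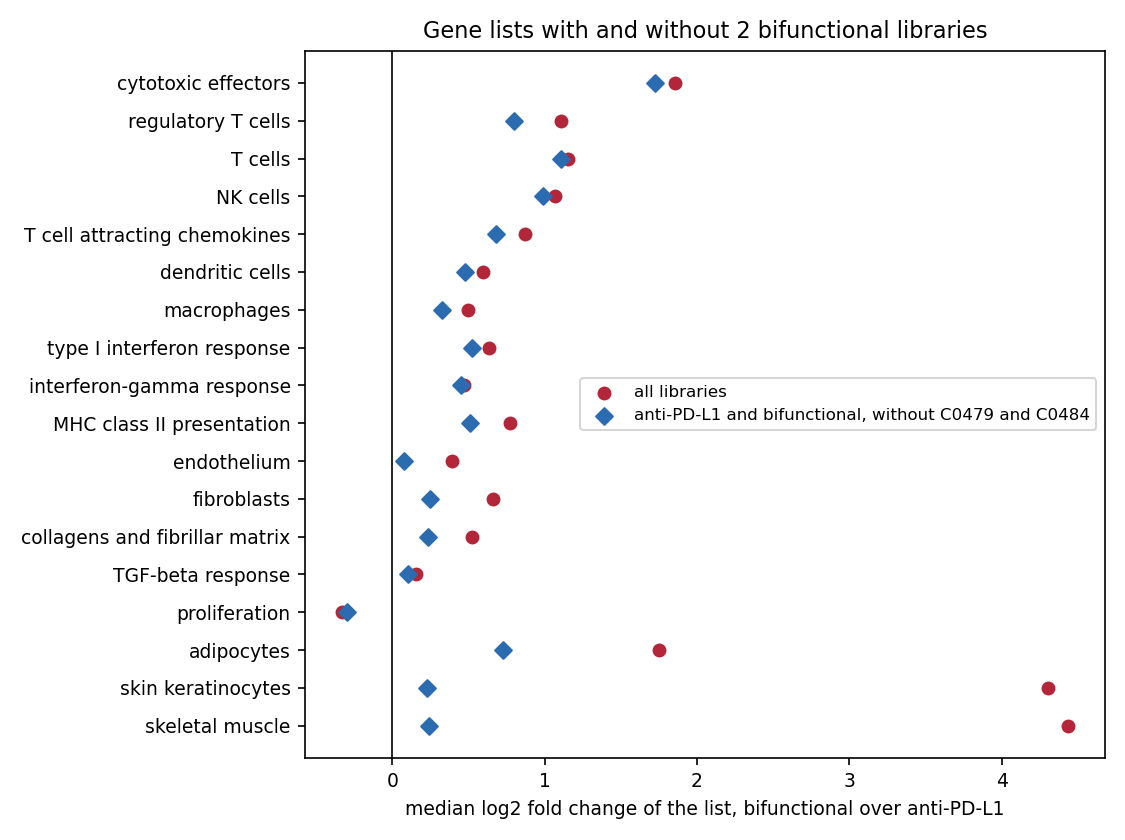
Median log2 fold change of 18 gene lists, bifunctional over anti-PD-L1 (horizontal axis), in all libraries (red circles) and in the anti-PD-L1 and bifunctional libraries without C0479 and C0484 (blue diamonds). The cytotoxic median lies at 1.86 and 1.72, while the keratinocyte median falls from 4.30 to 0.23.

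Cell division genes were lower in bifunctional tumors. Of 21 proliferation genes 8 fell (15 adjusted over the list alone), with a median of −0.33. Top2a, the topoisomerase that untangles replicated DNA, fell by 0.44 (SE 0.124, adjusted p = 0.023) to 335 ± 62.2 CPM (n = 10), and 0 of 10 bifunctional libraries lay above the anti-PD-L1 median. The mitotic kinases Cdk1 (−0.41, adjusted p = 0.0262) and Aurkb (−0.37, adjusted p = 0.018) and the cyclin Ccnb1 (−0.48, adjusted p = 0.0271) fell too. These 4 genes were not called in TPM, at −0.09 to −0.22, where the median of all genes lay at 0.157 with log2(TPM + 1) and 0.266 with log2(TPM + 0.1). Of 16 ribosomal protein genes 1 fell (0 adjusted over the list alone, median −0.25). Among 12 replication-dependent histone genes 1 rose and 1 fell; their median was −0.30, their mean 0.10, and camera placed the list down. In bifunctional vs anti-PD-L1 camera called proliferation (adjusted p = 5.64e-09), ribosomal proteins (0.000127) and histones (0.00537), none with an estimated correlation (adjusted p = 0.297, 0.421 and 0.523). The proliferation score was 6.049 ± 0.194 against 6.376 ± 0.086 (n = 10 each, permutation adjusted p = 0.00048).

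Among the drug targets, Cd274, which encodes PD-L1, rose by 0.78 (SE 0.244, adjusted p = 0.0341), from 7.70 ± 2.40 to 13.2 ± 7.02 CPM (n = 10 each), with 0.54 (adjusted p = 0.0815) once C0479 was left out. Pdcd1, which encodes PD-1, had 0.90 (SE 0.337, adjusted p = 0.0647), and passed in the 20 libraries alone (0.89, adjusted p = 0.0292). Tgfb1 had 0.40 (adjusted p = 0.125; 0.39 and 0.0479 in the 20 libraries), Tgfb2 −0.30, Tgfb3 0.08, Tgfbr1 0.19 and Tgfbr2 0.04, the last 4 not passing. In bifunctional vs anti-PD-L1, of 16 genes of TGF-β ligands, receptors and drug targets 3 rose (5 adjusted over the list alone, median 0.29, camera adjusted p = 0.0778). The list score was 4.863 ± 0.134 against 4.654 ± 0.138 (n = 10 each, permutation adjusted p = 0.00508, 9 of 10 libraries above). Of 16 TGF-β response genes 0 rose and 0 fell in edgeR, also adjusted over the list alone (median 0.16, camera adjusted p = 0.487).

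In the fit of all libraries edgeR called 1970 of 15183 genes between the bifunctional and anti-PD-L1 groups, 1363 higher and 607 lower, and DESeq2 called 2599. With only the 20 libraries compared, 3233 of 14592 genes passed (1662 higher, 1571 lower), of which 1743 were among the 1970. In those 20 libraries 10 of 13 cytotoxic, 10 of 13 T cell and 17 of 21 type I interferon genes rose, and 16 of 21 proliferation genes fell. The count of 3233 was 1662 without C0479, 1791 without C0484 and 727 without both, and in the last 8 of 13 cytotoxic, 7 of 13 T cell and 9 of 21 type I interferon genes rose while 10 of 21 proliferation genes fell. With muscle, skin and fat scores as covariates 87 genes passed in all libraries and 535 in the 20 libraries. In a separate fit of 2 groups over 15704 genes, 1823 were higher and 1722 lower against all 10 anti-PD-L1 libraries. Against only part of the anti-PD-L1 libraries 2 were higher and 0 lower, and the cause of this drop was not tested. Across genes the fold change in the 20 libraries had a Spearman rho of 0.205 with transcript length and 0.106 with GC content. A length trend was not removed.

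The comparison of the bifunctional protein with the trap control asks what binding of PD-L1 adds to the trap. Pooled over sets, macrophage and antigen presentation genes were higher with the bifunctional protein. Of 15 macrophage genes 14 rose (14 adjusted over the list alone, median 0.67), among them C1qc, a complement C1q subunit, at 0.91 (adjusted p = 0.00054), and the lysosomal marker Cd68 at 0.70 (adjusted p = 0.000795). Within set 2, with 4 trap control libraries, C1qc had 0.59 (edgeR adjusted p = 0.36) and Cd68 0.33 (adjusted p = 0.385), and 0 of 15 macrophage genes passed. Krt5 had 5.67 (adjusted p = 0.00044) pooled and 4.70 (adjusted p = 0.402) within set 2. Tgfb1 fell by 0.82 (adjusted p = 0.00149) pooled but had 0.03 (adjusted p = 0.946) within set 2, and 0.17 in pooled log2(TPM + 1), where the median of all genes lay at 0.533. The cytotoxic score was 1.920 ± 0.297 (n = 10) against 1.775 ± 0.304 (n = 4) within set 2 (exact permutation p = 0.422), and the NK cell score differed by −0.002 (exact permutation p = 0.984).

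Pooled, camera called 11 lists for bifunctional vs trap control. Besides macrophages (adjusted p = 2.18e-08), these were MHC class II (7 of 8 rose, median 0.98), cytotoxic effectors (4 of 13, 0.74), T cells (5 rose and 1 fell of 15, 0.68), matrix (16 rose and 2 fell of 33, 0.49), fibroblasts (10 of 14), alternative macrophage activation (4 of 7, 1.04), adipocytes (4 of 9, 1.84) and interferon-γ (6 rose and 1 fell of 20, 0.41). The other 2, mitochondrially encoded genes (13 of 13, −2.17) and immediate early genes (3 of 12, −0.46; in log2(TPM + 1) 0.40, with 0.533 for all genes), were lower. Within set 2 the medians of these 2 lists turned to 0.25 and 0.08, without a call (camera adjusted p = 0.0629 and 0.723). Adjusted over the list alone, 8 MHC class II and 8 adipocyte genes rose, and the other counts stayed as given. None held with an estimated correlation (adjusted p = 0.623). Within set 2 camera called 6 lists with 0 members past the threshold over all genes. Macrophages (median 0.51, adjusted p = 5.29e-07), MHC class II (0.51, adjusted p = 0.0444) and matrix (0.32, adjusted p = 0.0145) were higher. Proliferation (−0.28, adjusted p = 1.49e-09; 7 of 21 fell adjusted over the list alone), histones (−0.34, adjusted p = 1.39e-06; 10 of 12) and ribosomal proteins (−0.27, adjusted p = 2.96e-05; 3 of 16) were lower, while their pooled medians, 0.04, 0.07 and 0.15, were above 0 and not called by camera. With an estimated correlation none of the 6 held (adjusted p = 0.908). The TGF-β response list had a median of 0.04 within set 2, with 0 of 16 called (camera adjusted p = 0.723).

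edgeR called 5070 genes pooled (2436 higher, 2634 lower; DESeq2 5233) between the bifunctional and trap control groups. Within set 2 it called 0 of 15479 genes, with 1950 at an unadjusted p under 0.05, and with the set as a term 0, with 2506 at an unadjusted p under 0.05. A fit of the 3 groups of set 2 called 1, the pseudogene Ppp4r1l-ps, named here only because the count is 1. On simulated data of the size of set 2, 58% of genes changed 2-fold were recovered, and 24% of those changed 1.5-fold, with 7.9% false calls.

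The comparison of the trap control with the isotype control asks what the TGF-β trap does without PD-L1 binding. Sample numbers follow treatment within set 1 too, with the isotype control at C0449 to C0458 and the trap control at C0459 to C0464. A processing difference between these runs of numbers cannot be told apart from treatment. Pooled, cytotoxic and interferon genes were higher with the trap control. Of 13 cytotoxic genes 8 rose (10 adjusted over the list alone, median 1.05). Gzmb rose by 1.65 (SE 0.314, adjusted p = 0.000266), from 0.842 ± 0.394 to 2.62 ± 1.49 CPM (n = 10 each), and Nkg7 by 1.76 (SE 0.407, adjusted p = 0.00171). Within set 1, with 6 trap control libraries against 10, Gzmb had 1.03 (edgeR adjusted p = 0.0604) and 0 of 9 cytotoxic genes passed (1 adjusted over the list alone, median 0.57). The cytotoxic score was 1.448 ± 0.354 against 0.918 ± 0.256 pooled (n = 10 each, permutation adjusted p = 0.0162, 9 of 10 libraries above the isotype control median). In the 6 libraries of set 1 it was 1.230 ± 0.169 (exact permutation p = 0.0189, adjusted p = 0.339). Cldn5, a tight junction protein of endothelium, rose by 0.75 (SE 0.197, adjusted p = 0.00488) pooled and 0.81 (adjusted p = 0.0422) within set 1. Rps14, a ribosomal protein, fell by 0.44 (SE 0.15, adjusted p = 0.0248) pooled and by 0.68 (adjusted p = 0.0187) within set 1, with 0.05 in pooled log2(TPM + 1), where the median of all genes lay at 0.254.

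Pooled, camera called 7 lists for trap control vs isotype control: cytotoxic effectors (adjusted p = 0.00335), interferon-γ (11 of 20 rose, 13 adjusted over the list alone, median 0.41), type I interferon (11 of 21, 12 adjusted over the list alone, 0.42), MHC class I (6 of 13, 0.27), proliferation (10 rose and 1 fell of 21, 0.34), histones (11 rose and 1 fell of 12, 0.70) and mitochondrially encoded genes (0 of 13, −0.65). Within set 1 camera called cytotoxic effectors (adjusted p = 0.043), interferon-γ (0 of 19, median 0.22, adjusted p = 0.00682), type I interferon (0 of 21, 0.37, adjusted p = 0.00405), MHC class I (2 of 13, 5 adjusted over the list alone, 0.24, adjusted p = 0.00682) and endothelium (1 of 12, 8 adjusted over the list alone, 0.57, adjusted p = 0.0025), all higher. It called ribosomal proteins lower (2 of 16, 2 adjusted over the list alone, −0.13, adjusted p = 0.00682), whose pooled median was 0.14, and not proliferation (adjusted p = 0.904). With the GC trend described next removed, MHC class I was no longer called (0 of 13, 0.11, adjusted p = 0.0535), while the other 5 lists were. None of these held with an estimated correlation (adjusted p = 0.917 pooled and 0.981 within set 1). The TGF-β response genes were not called pooled (1 of 16 fell, median −0.13, camera adjusted p = 0.486) or within set 1 (0 of 16, median 0.03, camera adjusted p = 0.904). Skeletal muscle genes had the highest pooled median (8 of 9 rose, 5.98, camera adjusted p = 0.46), with library C0463 far above the rest of the trap control libraries of set 1.

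edgeR called 4213 genes pooled (2381 higher, 1832 lower; DESeq2 4465) for the trap control against the isotype control. Within set 1 it called 1041 of 14183 (589 lower, the rest higher), 707 of them shared with the pooled call, and with the set as a term 1568. Within set 1 the fold change across genes followed GC content, with a Spearman rho of 0.6; genes are not independent replicates. The median fold change was −0.29 in the tenth of genes lowest in GC and 0.24 in the tenth highest. With a GC trend removed from each library 13 genes passed, 8 of them among the 1041, Cldn5 had 0.59 (adjusted p = 0.264), and Rps14 still fell. The count was 504 without C0459, 534 without C0458 and 51 without both, the libraries highest in structural RNA in their groups. Without C0458 alone Cldn5 had 0.78 (adjusted p = 0.0673).

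**Figure D4:**
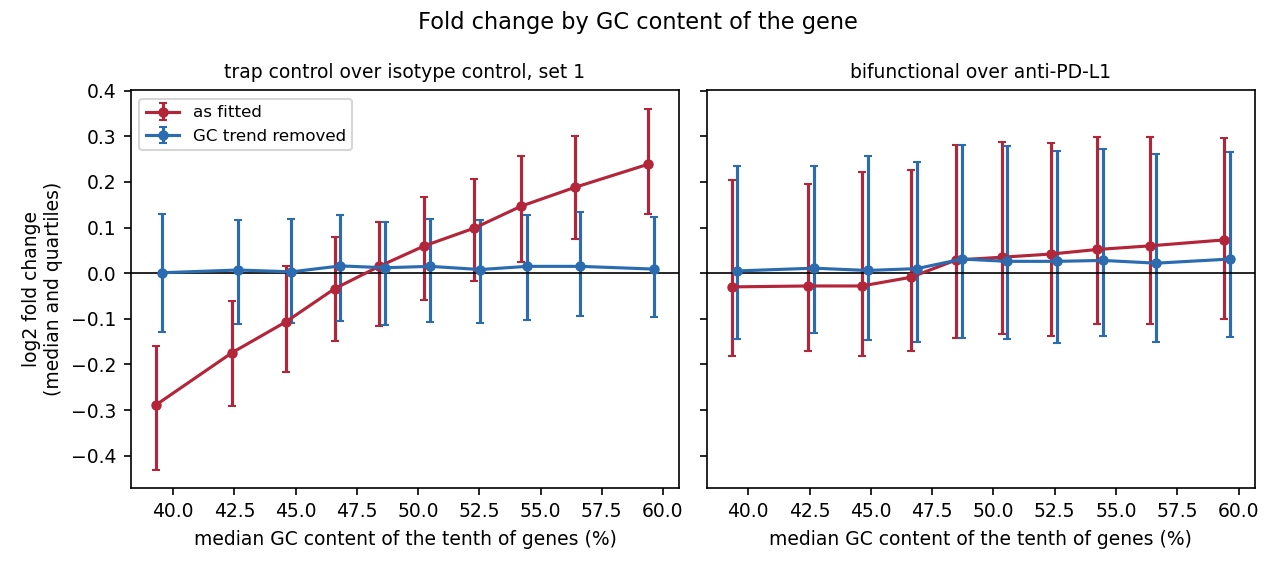
Log2 fold change (vertical axis, median with lower and upper quartile) for 10 bins of genes ordered by GC content (horizontal axis, median GC content of the bin in %), as fitted (red) and with a GC trend removed from each library (blue), for trap control over isotype control in set 1 (left) and bifunctional over anti-PD-L1 (right). On the left the median goes from −0.29 to 0.24 and after removal from 0.00 to 0.01; on the right it goes from −0.03 to 0.07 as fitted.

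The comparisons of anti-PD-L1 and of the bifunctional protein with the isotype control ask what each does by itself, and in both every treated library lies in set 2 and every control library in set 1. No value within a set can be had, and only the trap control group, present in both sets, lets the set enter as a term. Values with the set as a term therefore contain the trap control against isotype control difference of set 1, which followed GC content. No GC trend was removed from these fits. In anti-PD-L1 tumors, against the isotype control, the macrophage gene C1qa rose by 0.99 (adjusted p = 3.31e-05) and the mitotic regulator Cdc20 by 1.08 (adjusted p = 1.05e-07). The mitochondrial ATP synthase gene mt-Atp6 fell by 3.41 (SE 0.402, adjusted p = 7.82e-09) and Tgfb1 by 1.54 (SE 0.187, adjusted p = 1.35e-08). None of these 4 passed with the set as a term: C1qa had 0.37 (adjusted p = 0.708), Cdc20 0.22 (0.724), mt-Atp6 −0.32 (0.79) and Tgfb1 −0.28 (0.683). For anti-PD-L1 vs isotype control T cell genes were not called (1 rose and 2 fell of 15, median 0.15, camera adjusted p = 0.894), nor were cytotoxic genes (5 of 13 rose, 0.33, camera adjusted p = 0.68). The T cell score averaged 0.763 with anti-PD-L1 and 0.745 with the isotype control (n = 10 each, permutation adjusted p = 0.813).

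In bifunctional vs isotype control, all 13 cytotoxic genes rose in the pooled fit (13 adjusted over the list alone, median 1.78). Nkg7 rose by 3.00 (adjusted p = 6.7e-08) and Gzmb by 2.35 (adjusted p = 1.2e-07), and the complement gene C1qc by 1.53 (adjusted p = 2.54e-08). Nkg7 rose with the set as a term, by 2.33 (adjusted p = 0.0434), while Gzmb had 1.18 (adjusted p = 0.141) and C1qc 0.98 (adjusted p = 0.0678). mt-Atp6 fell by 3.04 (adjusted p = 7.64e-08) and Tgfb1 by 1.13 (adjusted p = 3.07e-06) pooled, with 0.05 (adjusted p = 0.957) and 0.13 (adjusted p = 0.789) with the set as a term; in log2(TPM + 1), where the median of all genes lay at 0.797, Tgfb1 had 0.04. Pooled, 14 of 15 macrophage genes rose (median 0.76), 8 of 8 MHC class II genes (1.96), 6 of 6 NK cell genes (1.53) and 11 of 14 fibroblast genes (1.24), while 13 of 13 mitochondrially encoded genes fell (−2.91). With the set as a term camera called cytotoxic effectors (1 of 13, median 0.73, adjusted p = 0.0468), macrophages (2 of 15, 9 adjusted over the list alone, 0.65, adjusted p = 1.24e-05), endothelium (0 of 12, 0.72, adjusted p = 0.00296), type I interferon (0 of 21, 0.35, adjusted p = 0.00218), interferon-γ (0 of 20, 0.31, adjusted p = 0.0133) and MHC class I (0 of 13, 0.29, adjusted p = 0.0468) higher. It called proliferation (0 of 21, −0.27, adjusted p = 5.54e-05) and ribosomal proteins (2 of 16, 3 adjusted over the list alone, −0.41, adjusted p = 1.34e-07) lower, whose pooled medians were 0.38 and 0.23. The mitochondrially encoded list turned to 0.27 with the set, without a call (adjusted p = 0.951). No list held with an estimated correlation, where the adjusted p was 0.98 with the set as a term and at least 0.716 pooled.

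Against the isotype control edgeR called 9664 genes for anti-PD-L1 (4811 higher, 4853 lower; DESeq2 9771) and 9813 for the bifunctional protein (5401 higher, 4412 lower; DESeq2 9876). With the set as a term these were 2 (Cyhr1 higher and Gm17711 lower, named because the count is so small; 1525 at an unadjusted p under 0.05) and 387 (138 higher, 249 lower; 209 shared with the pooled call). For anti-PD-L1 vs isotype control camera called pooled rises in proliferation (18 rose and 2 fell of 21, median 0.69), histones (11 rose and 1 fell of 12, 1.06) and ribosomal proteins (11 rose and 1 fell of 16, 0.47), and falls in mitochondrially encoded (13 of 13, −3.28) and immediate early genes (9 of 12, −0.86; in log2(TPM + 1) 0.27, with 0.575 for all genes). None held with an estimated correlation (adjusted p = 0.987). With the set as a term it called NK cells lower (0 of 6, 1 fell adjusted over the list alone, −1.02, adjusted p = 0.0217; pooled median 0.31), MHC class I higher (0 of 13, 0.19, adjusted p = 0.0397) and ribosomal proteins lower (0 of 16, −0.13, adjusted p = 0.0373), with adjusted p = 0.966 at an estimated correlation. The pooled NK cell score was the other way, 0.381 ± 0.083 with anti-PD-L1 and 0.278 ± 0.103 with the isotype control (n = 10 each, permutation adjusted p = 0.0401, 10 of 10 libraries above).

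The interaction of the 2 arms asks whether the trap changed expression differently with and without PD-L1 binding. A negative value means that a gene went lower, or rose less, between bifunctional and anti-PD-L1 than between trap control and isotype control. With the set as a term, the trap control and isotype control libraries compared are those of set 1, where fold changes followed GC content. No GC trend was removed from the interaction. Pooled, 15 of 21 proliferation genes were lower by this measure (17 adjusted over the list alone, median −0.67), among them Cdc20 at −1.09 (SE 0.208, adjusted p = 0.000735) and the replication helicase Mcm7 at −0.83 (adjusted p = 0.00133). Their values were, with the set as a term, −0.68 (adjusted p = 0.0144) and −0.46 (adjusted p = 0.0294), and 4 of 21 proliferation genes passed (10 adjusted over the list alone, median −0.33). The interleukin receptor Il2ra of activated and regulatory T cells was higher at 1.11 (adjusted p = 0.00441) pooled and 1.14 (adjusted p = 0.0215) with the set, and Vwf at 1.77 (adjusted p = 0.00301) and 1.55 (adjusted p = 0.0307). Hist2h2ac, a histone gene of a multigene family, had −1.31 (adjusted p = 0.000553) and −0.84 (adjusted p = 0.0104). In TPM none of these 5 genes passed, with adjusted p from 0.0691 to 0.275.

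camera called proliferation (adjusted p = 1.07e-06), ribosomal proteins (5 of 16 lower, 7 adjusted over the list alone, −0.34, adjusted p = 0.0317) and histones (11 lower and 1 higher of 12, median −0.97, mean −0.33, adjusted p = 2.5e-05) lower in the interaction of the 2 arms, and mitochondrially encoded genes higher (0 of 13, 0.97, adjusted p = 0.000588). It called, with the set as a term, matrix higher (5 of 33, 8 adjusted over the list alone, 0.57, adjusted p = 0.0132), proliferation lower (adjusted p = 6.44e-06), and histones lower although their mean was 0.05 (median −0.59). None held with an estimated correlation (adjusted p = 0.989 pooled and 0.852 with the set). Cytotoxic effectors were not called in the pooled interaction (0 of 13, median 0.10, camera adjusted p = 0.83), which carries the difference between the sets. edgeR called 3920 genes pooled (1771 higher, 2149 lower; DESeq2 4366) and 1320 with the set as a term, 1128 of them shared. In log2(TPM + 1) 149 passed.

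Fold changes of the 3 treatments against the isotype control share the control libraries, and in part the difference between sets. Across genes, which are not independent replicates, the correlation of the anti-PD-L1 and bifunctional fold changes was 0.850, where simulated unchanged groups against the same controls gave 0.531. With the controls split into separate groups of 5 it was 0.676, where the highest of 20 simulations of unchanged groups gave 0.0618. Both drugs had 4158 genes higher in common, with 1892 from independent calls, and 4073 lower, with 1491. The values of this paragraph come from fits of 2 groups at a time, whose counts differ from those of the fit of all libraries. Against the isotype control these called 5384 genes higher and 4932 lower for anti-PD-L1, and 5335 and 4590 for the bifunctional protein. For the trap control they called 1579 higher and 1298 lower. Trap control and bifunctional fold changes had a correlation of 0.792 (simulated 0.508; split controls 0.703, highest simulated 0.0432), with 1414 genes higher in both (independent 555) and 1205 lower (392). Trap control and anti-PD-L1 had 0.710 (simulated 0.520; split controls 0.482, highest simulated 0.0566), with 1447 higher in both (560) and 1143 lower (422). Within set 2, trap control and bifunctional fold changes against anti-PD-L1 had a correlation of 0.565, with 0.368 simulated, and 0.379 with the anti-PD-L1 libraries split, where the highest simulation gave 0.101. For the trap control of set 2 against anti-PD-L1, 0 genes were called higher and 0 lower, with the anti-PD-L1 libraries shared or split. For the bifunctional protein 1823 were called higher and 1722 lower, but 2 and 0 with the anti-PD-L1 libraries split. Each split of this paragraph was a single random draw. The simulated genes vary independently of each other, which real genes do not. The simulations also held no difference between the library sets. For anti-PD-L1 and the bifunctional protein all treated libraries lie in set 2 and all isotype control libraries in set 1. The set alone could thus give a high correlation and many shared genes there, with the controls shared or split.

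Correlations of list scores across tumors were computed within groups, 16 in all, and none passed after adjustment (smallest adjusted p = 0.106). In the 10 bifunctional tumors the T cell score went with the matrix score (Pearson r 0.736, permutation p = 0.0139; Spearman rho 0.697, permutation p = 0.0303), with r = 0.598 without C0479 and C0480, the libraries farthest from the median T cell score. In the 10 anti-PD-L1 tumors the T cell score went with the interferon-γ score by r (0.703, permutation p = 0.0199) but not by rho (0.442, permutation p = 0.205), and r was 0.154 without C0471 and C0473, so the relation rests on those samples. In the 6 trap control libraries of set 1 T cells and matrix gave r = 0.745 (exact permutation p = 0.0111; rho 0.943, exact permutation p = 0.0167), and 0.338 without C0459 and C0464. The 4 trap control libraries of set 2 are too few for a correlation.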

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

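Apart from the joint test of GC content and transcript length on the library sets and the test of GC content on trap control against isotype control, the tests of explanations in this part were chosen only after the results were seen. Each list score, library depth and named gene was also checked for a library that stood apart from its group, with the trap control group checked as its 6 and its 4 libraries. Of 310 groups of values 29 held such a library, where chance alone gives about 1 in 20, or 15.5. The value given for each is the gap to the nearest other library divided by the range of the group, and a level is set against the median of the other libraries of the group.

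The libraries C0449 to C0464 and C0465 to C0488 differ in structural RNA and in many genes. Treatment as the whole cause is argued against by the trap control group, where 6997 genes differed between 6 and 4 libraries that received the same protein. A difference in library preparation or sequencing that follows the sample numbers may account for the sets: the 6 set 1 libraries of the trap control lie at one end of the sample numbers of their group (exact chance of lying at either end 0.00952), but this order was seen before it was tested and the labels name no batch, so it stays a hypothesis. A one-way trend with GC content is argued against by a Spearman rho of 0.032 with the set effect across genes, while transcript length, at 0.169, lies between the bounds set beforehand and stays open. For anti-PD-L1 and the bifunctional protein against the isotype control, the set and the treatment cannot be told apart without the bridge that the 10 trap control libraries give.

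Cytotoxic, T cell and interferon genes were higher with the bifunctional protein than with anti-PD-L1. Of 40 splits of these 20 libraries only the real one reached 3233 called genes (highest other 0). In all libraries only the real one reached 1970 (highest other 25). This is the smallest share that 40 splits can give, and it counts all genes, not these lists. The splits mix the sample numbers, so they do not test an effect of processing order. Host tissue is argued against as the whole cause for the cytotoxic list in bifunctional vs anti-PD-L1, with a median of 1.722 and 8 of 13 genes higher without C0479 and C0484, and 1.49 and 6 of 13 with host tissue scores as covariates; with these covariates 87 genes passed in all, among them 2 of 15 T cell, 1 of 21 type I interferon and 0 of 20 interferon-γ genes in edgeR (medians 0.98, 0.56 and 0.43), so a part played by host tissue stays open for those lists. Structural RNA share is argued against as well for the cytotoxic list, with a median of 1.885 when it entered as a covariate. A lower share of tumor cells would raise all other cell types by the same fold. With endothelium as the only cell type set beside them, this is argued against as the whole cause for the cytotoxic and T cell lists. The mean fold of their genes was higher by 1.33 and 0.99 on the log2 scale and that of endothelium by 0.37 (two-sided permutation p of the differences 0.00803 and 0.00388, n = 10 each). The list scores, which compress genes near 1 CPM, differed by 0.369 for T cells and 0.352 for endothelium (permutation p of the difference 0.924). The fold scale was chosen after the results were seen. Other non-tumor lists, some with higher medians than endothelium, were not compared in this way, so the argument rests on endothelium and on this scale. More cytotoxic lymphocytes or a change within cells could account for the cytotoxic and T cell lists. Whether both arms are needed stays open. The cytotoxic score was 1.775 in the 4 trap control libraries of set 2 against 1.920 with the bifunctional protein (exact permutation p = 0.422) and 1.066 with anti-PD-L1. In the pooled interaction 0 of 13 cytotoxic genes passed, but this cannot decide the question, because its trap control libraries come from both sets and its isotype control libraries from set 1. The cytotoxic score differed between trap control and isotype control by 0.53 pooled and by 0.312 within set 1.

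The genes that differed between trap control and isotype control in set 1 followed GC content, with a rho of 0.6 across genes, as was predicted before the test if GC bias were the cause. With the trend removed 13 genes passed, 8 of them among the 1041, and on simulated data with such a trend 72.2% of 490 calls were false without the removal and 4.5% of 134 with it. A linear effect of structural RNA share is argued against as the whole cause, since 1137 genes passed with it as a covariate. But 51 passed without C0458 and C0459, the libraries highest in it, so a part played by these libraries stays open. Of 40 splits only the real one reached 1041 genes (highest other 1). Within set 1 the isotype control holds C0449 to C0458 and the trap control C0459 to C0464. A processing difference that follows these numbers cannot be told apart from treatment, and the splits, which mix the numbers, do not test it. An action of the trap by itself may add to the differences in set 1. With the trend removed the cytotoxic list still had a median of 0.54 (camera adjusted p = 0.00204, but adjusted p = 0.731 with an estimated correlation), with 0 of its 9 genes called by edgeR. Cldn5 had 0.81 before the removal and 0.59 (adjusted p = 0.264) after it.

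For the remaining counts of genes, 40 splits of the same libraries were counted as well. Pooled over sets, 1 split of 40, the real one, reached the counts of 4213 for the trap control (highest other 3355), 9664 for anti-PD-L1 (0) and 9813 for the bifunctional protein (15) against the isotype control, and 5070 for the bifunctional protein against the trap control (1238). This is the smallest share that 40 splits can give, and it was not adjusted for the number of counts tested. The real groups also follow the library sets, and the split that gave 3355 genes put 6 set 1 libraries in one group and 10 in the other. For the interaction 2 of 40 splits reached 3920 genes, so chance was not excluded. The highest, 5664, came from a split that placed 8 of the set 1 libraries with the bifunctional group. With the set as a term only the real split reached 1320 for the interaction (highest other 176). The same held for 387 for the bifunctional protein against the isotype control (highest other 67). For anti-PD-L1 chance was not excluded (2 genes, reached in 4 of 40 splits, highest other 241). With the set as a term these values use the trap control against isotype control difference of set 1, which followed GC content. No GC trend was removed from these fits, so a part played by it stays open. For the bifunctional protein against the trap control within set 2 the real count was 0, which all 40 splits reach by construction, so they say nothing on chance (highest other 691). The single splits with 241 and 691 genes point to some structure among the samples, although the median of the other splits was 0 in both cases, and what it is was not tested.

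The 5 genes named in the interaction were chosen because they passed the test of a difference between the trap's effects with and without PD-L1 binding: Cdc20 (adjusted p = 0.000735), Mcm7 (0.00133), Il2ra (0.00441), Vwf (0.00301) and Hist2h2ac (0.000553), and none of them passed in TPM.

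In the isotype control group, C0449 was the highest in skeletal muscle (a score of 3.43 against 0.25, value 0.736), and stood apart in inflammatory cytokines (0.504) and neutrophils (0.483), and C0455 in skin keratinocytes (0.563). In the anti-PD-L1 group, C0475 was far above the rest in skeletal muscle (4.14 against 0.247, value 0.967) and in Ckm (0.949). C0478 stood apart in contractile genes (0.479) and endothelium (0.715), C0473 in Cd6 (0.481), and C0469 was the lowest in drug targets (0.541).

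Among the 6 trap control libraries of set 1, C0464 stood apart in MHC class II (4.61 against 2.72, value 0.729), interferon-γ genes (0.661), T cell attracting chemokines (0.85) and epithelial genes (0.719). C0463 was far above the rest in skeletal muscle (9.23 against 0.244, value 0.946) and the lowest in TGF-β response (0.629). C0460 was the lowest in cytotoxic effectors (0.821) and stood apart in Krt5 (0.702), and C0459 was the highest in erythroid genes (6.85 against 3.72, value 0.645). Among the 4 of set 2, C0465 stood apart in Nkg7 (0.932) and Cd68 (0.912), C0466 in matrix (lowest, 0.843) and ribosomal proteins (0.967), and C0467 in histones (0.916) and Cdc20 (0.853).

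In the bifunctional group all 4 such values were in C0479: it was the highest in skin keratinocytes (8.15 against 1.38, value 0.646) and in Krt5 (0.56), and the lowest in histones (0.512) and Hist2h2ac (0.52).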

How the results depend on the processing

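No paired analysis was possible because each sample number belongs to 1 mouse and 1 group. The fits with the library set, the structural RNA share, left-out libraries, a GC trend removed and the 3 groups of set 2 were chosen only after the results were seen. Where a value below differs from the report's, the cause was not tested, apart from points that hold by construction. Fits of fewer libraries or genes have less to work with. The fit of all libraries, with 1 mean per group, counts the difference between the sets within the trap control group as spread in all its tests.

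Scaling by DESeq2 size factors, no filter, a filter at a mean of 1 CPM and the DESeq2 test kept all 6 counts of changed genes within 1.5 times of the value in all libraries. For the bifunctional protein against anti-PD-L1, 61 values of the 34 genes followed through the settings no longer passed under some setting, 12 newly passed and 0 reversed. The host tissue covariates ended the most calls, 21 of 34, and without C0479 and C0484 5 of 31 were lost.

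Apart from the construction of the fits described above, the cause of changes in the counts was not tested. Counts of changed genes moved as follows. For trap control against isotype control (4213) they were 1568 with the set as a term, 1041 within set 1, 1137 with structural RNA share as a covariate there, 13 with the GC trend removed, 51 without C0458 and C0459, and 504 to 534 without either. Against the isotype control the set as a term gave 2 for anti-PD-L1 (9664) and 387 for the bifunctional protein (9813). For bifunctional against anti-PD-L1 (1970) they were 3233 in the groups compared, 3934 with the set as a term, 3498 with structural RNA share, 3095 with the GC trend removed, 4014 with 3 groups in the fit, 727 without C0479 and C0484, 87 with host covariates and 535 with these in the groups compared. For bifunctional against trap control (5070) they were 2890 in the groups compared, 836 with host covariates, 12986 in log2(TPM + 1) and 12979 in log2(TPM + 0.1). There edgeR gave 0 with the set as a term (2506 at an unadjusted p under 0.05), 0 within set 2 (1950), 0 with structural RNA share (1833), 0 with the GC trend removed (1963), and 1 with 3 groups in the fit. For the interaction (3920) they were 149 and 168 in the TPM scales, 1320 with the set and 1166 with set and structural RNA share.

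TPM shifts all genes: the median log2 fold change was 0.254 and 0.434 for trap control, 0.575 and 0.991 for anti-PD-L1 and 0.797 and 1.304 for the bifunctional protein against the isotype control, and 0.533 and 0.859 for bifunctional against trap control (pseudocounts 1 and 0.1). Of the called genes 95.7%, 94.2%, 97.6% and 99.4% were then higher, against 56.5%, 49.8%, 55.0% and 48.0% in the counts. For bifunctional against anti-PD-L1 98.8% were higher in TPM, 69.2% in all libraries, 51.4% in the 20 libraries and 38.7% without C0479 and C0484. For the interaction 89.3% were higher in TPM and 45.2% in the counts.

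Values that reversed were as follows; the cause was not tested. Tgfb1 in bifunctional against trap control (−0.82) had 0.17 and 0.22 in the TPM scales, 0.054 with the set as a term, 0.032 within set 2, 0.022 with structural RNA share, 0.032 with the GC trend removed and 0.028 with 3 groups. Tgfb1 in bifunctional against isotype control (−1.13) had 0.038 and 0.038 in TPM and 0.125 with the set. mt-Atp6 there (−3.04) had 0.048 with the set. Rps14 in trap control against isotype control (−0.44) had 0.052 and 0.051 in TPM. The TPM values of these genes lie below the median of all genes in that scale, so relative to it they did not turn.

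Lists called by camera went to 0 in all 6 comparisons with an estimated correlation, where at a preset one 7, 5 and 12 were called against the isotype control (trap control, anti-PD-L1, bifunctional), 18 and 11 for bifunctional against anti-PD-L1 and trap control, and 4 in the interaction. fry called 16 for anti-PD-L1 and 24 for bifunctional against the isotype control. The set as a term gave 3 for anti-PD-L1 and 6 for bifunctional against trap control, which had 6 within set 2. TPM gave 5 for bifunctional against isotype control, 3 against trap control and 10 in the interaction. List scores that differed went from 2 to 0 in TPM and 0 within set 1 for trap control against isotype control, from 22 to 35 in TPM for anti-PD-L1, and for bifunctional against trap control from 7 to 34 in TPM, 4 with medians over members and 0 within set 2. The cause was not tested.

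Depth limits the genes near 1 CPM, which before TMM scaling is 13.5 to 27.7 counts in a library. After scaling, the counts behind 1 CPM also depend on the scaling factor of the library. Several T cell genes lie near or below 1 CPM, and Cd6, Ckm and Ctla4 fell below the filter in the 20 libraries. The median log2(CPM + 1), which is 1 at 1 CPM, was 0.217 for Cd6 in the anti-PD-L1 libraries other than C0473. It was 0.526 for Nkg7 in the set 2 trap control libraries other than C0465. On simulated data for bifunctional against anti-PD-L1, the fit of the 20 libraries compared recovered 83% of 2-fold and 55% of 1.5-fold changes, with 4.2% false calls. For the fit of all libraries these were 73%, 49% and 5.4%.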

Other observations

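Of the tests in this part, the 3 on host tissue and on the shared trap arm were chosen only after the results were seen. Several cell types and pathways had no called gene in bifunctional vs anti-PD-L1 in the fit of all libraries. In edgeR 0 of 10 neutrophil genes (median 0.37, camera adjusted p = 0.195), 0 of 7 genes of alternative macrophage activation (0.67, adjusted p = 0.487), 0 of 13 inflammatory cytokines (0.11, adjusted p = 0.487, with camera's direction down), 0 of 5 mast cell and eosinophil genes (1.09, adjusted p = 0.864, direction down) and 0 of 5 erythroid genes (0.32, adjusted p = 0.487) passed over all genes, and 0 adjusted over the list alone. The same holds for 15 genes of hypoxia and glycolysis (median −0.01, adjusted p = 0.554), 12 immediate early genes (0.33, adjusted p = 0.131) and 13 mitochondrially encoded genes (0.29, adjusted p = 0.453). With only the 20 libraries compared, 3 of 13 mitochondrially encoded genes rose (4 adjusted over the list alone, median 0.27, camera adjusted p = 0.0109, adjusted p = 0.553 with an estimated correlation), as did 1 of 12 immediate early genes (1 adjusted over the list alone, camera adjusted p = 0.0599), and 0 genes of the other lists. In bifunctional against trap control tumors within set 2, the 4 measured B and plasma cell genes had a median of 0.46 (camera adjusted p = 0.419) with 0 called.

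Some genes of epithelial and mesenchymal state were higher with the bifunctional protein. Of 13 epithelial genes 3 rose and 1 fell (9 and 1 adjusted over the list alone, median 1.09, camera adjusted p = 0.202), of 12 genes of mesenchymal transition 3 rose (4 adjusted over the list alone, 0.24, adjusted p = 0.1), and of 12 contractile genes 2 rose (2 adjusted over the list alone, 0.39, adjusted p = 0.487). Of 3 mammary epithelium and milk genes 0 passed (2 adjusted over the list alone, median 1.30, adjusted p = 0.699).

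A hypothesis is that skin next to the tumor was sampled with C0479 and C0484, where the keratinocyte score was 8.15 and 3.16. Muscle genes were not confined to these libraries, with scores of 7.06 and 7.99 there, and 3.31 and 3.47 in C0480 and C0481. Without C0479 and C0484 the keratinocyte list had a median of 0.226, against 4.30 with them, so skin in these libraries may account for the keratinocyte genes. For the collagen and matrix list host tissue of C0479 and C0484 is argued against as the only source, since 5 of its members were called without these libraries, although the median went from 0.52 to 0.23. Host tissue in the other libraries stays open for this list.

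Another hypothesis is that the TGF-β trap, present in both the trap control and the bifunctional protein, moved the same genes in set 2. Against separate groups of anti-PD-L1 libraries, the fold changes of both had a covariance across genes of 0.0227, and permuted labels gave a 95th percentile of 0.0239 over the 24 libraries (one-sided permutation p = 0.0572). In the edgeR fits of the same split the covariance was 0.109 and the correlation 0.379, above the highest of 20 simulations of unchanged groups (0.0159 and 0.101), but these simulate genes as independent, which permuting labels does not. A shared effect of the trap arm is thus possible and stays open, with 4 trap control libraries in set 2.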
